A study of Bos taurus with 34 samples.

How the data were processed

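The series describes RNA sequencing of the inner lining of the reproductive tract of 5 nulliparous Holstein heifers, numbered 10872, 10882, 11033, 11070 and 11110 in the labels. The animals were synchronised with a progesterone-insert protocol and sampled on day 2 after ovulation. The lining of the ampulla, a part of the oviduct, is the endosalpinx. The ampulla, the upper uterine horn and the mid uterine horn were sampled on the ovulatory (ipsilateral) and the opposite (contralateral) side, and the uterine body once per animal by the labels, although the design text reads as if both sides were taken. That gives 34 libraries in 7 groups, with the ipsilateral upper horn of heifer 11110 not analysed here. Total RNA was extracted with a column microkit after bead homogenisation, and libraries were made with a stranded kit, per the labels' protocols.

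The authors deposited 1 table of read counts, whole numbers that were not normalised, with 1 column per library. Cutadapt, STAR 2.7.9a, HTSeq and SAMtools are named per the submitters' processing notes, without their roles. The genome build, the annotation release, the strand setting and the counting mode are not given in the sources used here. The table holds 38568 annotated features with at least 1 count, most of them named by single transcript accessions.

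Gene names were taken from a RefSeq gene table of assembly ARS-UCD2.0, which served for names only, and no coordinates were used. Of the features, 26362 were matched to 21554 genes and carried 95.3% of all counts, while 12206 stayed unmatched. An official symbol was carried by 19032 of the matched features. Where a gene had several features, which held for 3550 genes, the feature with the highest mean count stood for it in gene lists.

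Counting by transcript can lower the level of a gene, since a read shared by several of its transcripts can be lost. Genes with 1 annotated transcript had a median total of 4079 counts over all libraries, those with 2 had 468, those with 3 or 4 had 197 and those with 5 or more had 166, among genes with a feature. With genes without a feature set at 0 these medians were 170, 127, 34 and 29. The features of FN1, which codes for fibronectin, and IGF1 had 3 and 22 counts, and those of ESR1, the oestrogen receptor, 123 and 78. Levels are therefore comparable between libraries for 1 feature, and levels of different genes are not a measure of their relative expression. Multigene families, immunoglobulins and overlapping or antisense genes are uncertain for the same reason, as the handling of shared reads and of strand is unknown.

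Total counts per library ran from 11619486 to 30412782, with a median of 20610100. CPM, the counts scaled to the library total, were computed here from the deposited counts with TMM factors, and a mean ± SD was taken over heifers after averaging a heifer's libraries of the region. Ratios that rest on 1 to 3 counts in a group carry exact counting intervals. Where a whole compared region or side had 0 counts, the fold is a lower bound set at 3 counts over its libraries. Such intervals and bounds cover counting error only.

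Tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, robust dispersion estimates and the quasi-likelihood F test, with group and heifer as terms and all 34 libraries in each fit. The filter kept 17241 transcripts. The 9 contrasts were fixed before the data were examined, as were the gene lists, the ligand catalogue, the naming rule and most alternatives. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and calls were made at an adjusted p under 0.05. An SE is that of the edgeR log2 fold change. For the endometrium, the upper horn, the mid horn and the body had equal weight.

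The heifer block rests on the labels, which put all sites in the same animals. As a check, deviations from group means correlated within heifers with a median of 0.207 over 99 library pairs, and with -0.0539 over 396 pairs from different heifers and groups. No pair of libraries of the same group agreed within sampling noise: over 66 pairs, the chi-square per transcript with at least 20 counts was at least 45.0.

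There were 25 gene lists: ciliated epithelium, oviduct secretory epithelium, endometrial glands, general epithelium, smooth muscle, stroma, endothelium, erythroid cells, leukocytes, mesothelium, ovarian follicle and luteal cells, immediate early genes, proliferation, HOX genes, Müllerian duct regulators, hormone receptors, prostaglandin synthesis and transport, nutrient transporters, ion and bicarbonate transport, sperm-oviduct interaction, complement and antimicrobial genes, interferon-stimulated genes, matrix remodelling, antioxidant enzymes and candidate embryokines. Embryokines are maternal signals that act on the embryo. Secreted signals were held in a catalogue of 345 ligands in 16 families. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation was run beside it.

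Named genes carry a symbol and follow a fixed rule. For regions they were the 8 highest and the 8 lowest log2 fold changes among calls with the same sign in every heifer and at least 10 CPM in the higher group. For sides the limit was 5 CPM, and where nothing passed, the 3 transcripts with the lowest p in each direction were taken. For the interaction they were the 5 with the lowest p. Ligands were the 10 with the highest CPM in the ampulla and in the endometrium, with the 6 highest and 6 lowest fold changes among calls with at least 5 CPM. Each list could give up to 4 members with the smallest p. After values had been seen, the text was limited to the 3 lowest for comparisons other than the ampulla against the endometrium, and to none for the interaction. A few items that the rule selects are not reported here. Candidate embryokines could all be named, and those named between the ampulla and the endometrium are limited to calls and a few others.

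Alternatives fixed in advance were no expression filter, the DESeq2 1.42.0 Wald test, DESeq2 size factors, no heifer block, limma-voom with heifer as a random effect, fits of the compared groups alone, counts summed over sides, the ampulla against the upper horn alone, other rules for ligand detection, camera with an estimated correlation, and each heifer left out. Chosen after the data had been seen were counts summed per gene and the omission of the 3 doubted libraries named with the components, of the contralateral mid horn library of heifer 10882, of ribosomal and mitochondrial transcripts and, for gene lists, of the body library of heifer 11033.

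The procedure was tested on simulated counts for 16364 transcripts with known changes. For the ampulla against the endometrium edgeR recovered 46.7% of 2-fold and 95.8% of 4-fold changes, and for the mid horn against the body 32.6% and 64.6%. The upper horn gave 30.2% and 87.2% against the mid horn, and 29.3% and 68.9% against the body. The sides gave 12.8% and 52.1% in the ampulla, 10.3% and 46.9% in the upper horn, 10.5% and 43.0% in the mid horn, and 1.05% and 17.0% over all regions. The interaction gave 5.32% and 35.1%. False calls made up 1.79% to 7.58% of calls by edgeR, 8.99% to 21.9% by DESeq2 and 1.64% to 9.09% by limma-voom. For the first comparison, camera called 5 of 5 raised and 0 of 100 unchanged lists of 20 transcripts. The preset was not tested on correlated genes.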

Results

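RNA was measured in 34 libraries from the oviduct and uterine lining of 5 heifers on day 2 after ovulation. Each group held 5 heifers, except the ipsilateral upper horn with 4. The series title asks which embryokines, maternal signals that may act on the embryo, each part of the tract expresses. The smallest library, with 11619486 counts, was the contralateral upper horn of heifer 11033. Log2 fold changes are given ± SE and CPM as mean ± SD over heifers.

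The ampulla and the endometrium were separated by the first principal component, which took 52.5% of the variance, while the second took 12.5% and the third 7.56%. Ampulla libraries lay between -188 and -141 on component 1 and endometrium libraries between 38.5 and 95.8, except 1. That library, the contralateral mid horn of heifer 10882, lay at 11.9 and carried oviduct transcripts. In it KRT5, a keratin of basal epithelial cells, stood at 454 CPM against 0.718 in the other 4 uterine libraries of that heifer and 960 in its ampulla. With the 2 libraries that held the fewest features, the contralateral upper horn of heifer 11033 (16049) and the contralateral ampulla of 11070 (15773), this library makes the 3 doubted libraries. A nuclear 18S ribosomal transcript took 23.5% of counts in the body library of heifer 11033 and 19.6% in the contralateral upper horn library of heifer 10882, and 11.1% in the contralateral ampulla library of heifer 11110.

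**Figure D1:**
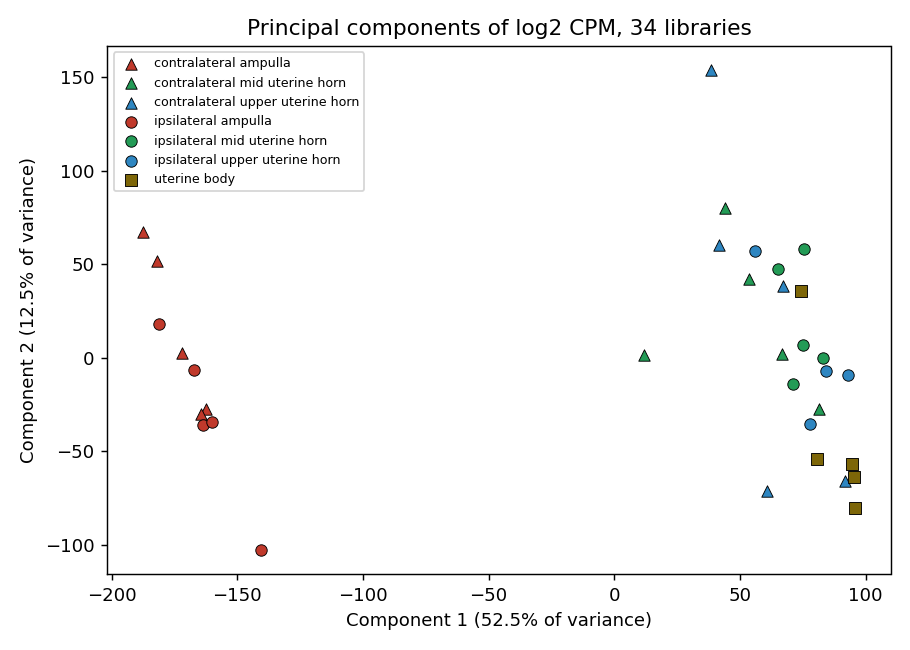
Scores of the 34 libraries on the first and second principal components of log2 CPM, in score units, with 52.5% and 12.5% of the variance; each point is a library, coloured by region and shaped by side. The ampulla libraries lie between -188 and -141 on component 1, and the contralateral mid horn library of heifer 10882 lies at 11.9.

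The ampulla against the endometrium asked how the oviduct lining differs from that of the uterus. Ampulla samples held more RNA of ciliated, secretory and general epithelium genes, and endometrium samples more of stroma, vessel, smooth muscle, leukocyte and HOX genes. With an estimated correlation the calls for stroma, endothelium and HOX genes held and those for the other 5 were lost (adjusted p 0.11 to 0.238). Ciliated epithelium genes had a median log2 of 2.65 and stromal genes one of -8.62 (n = 5 heifers). As stromal and vessel genes were so low in the ampulla, changes by region and by cell content cannot be told apart. Of 17241 transcripts tested with edgeR, 11198 were called, 5062 higher and 6136 lower in the ampulla. With DESeq2 size factors the split was 4688 to 6598. At least 2-fold were 3201 higher and 4865 lower calls, and 3062 and 3669 of all calls carried a symbol. The median over all transcripts was -0.18.

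The highest fold changes toward the ampulla, all in the same direction in 5 of 5 heifers by the naming rule, began with LRCOL1 at a log2 fold change of 11.04 ± 0.74, with 63.2 ± 21.1 CPM in the ampulla and 0.831 ± 1.71 in the endometrium. AQP9, a channel for water and small solutes, followed at 10.71 ± 0.61 and P2RX2, an ATP-gated ion channel, at 10.33 ± 0.58. CRISP3, a cysteine-rich secretory protein, rose by 9.59 ± 0.83 and KRT5 by 9.03 ± 0.76, to 1162 ± 279 CPM. TMEM151A stood at 8.96 ± 0.66, the gap-junction gene GJB7 at 8.90 ± 0.68 and SPRY4, an inhibitor of receptor tyrosine kinase signalling, at 8.51 ± 0.64. The endometrial means include the library of heifer 10882 described above, which held 23.2, 1.69, 6.40, 15.8, 454, 30.8, 17.8 and 2.38 CPM of these 8 in turn.

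Toward the endometrium, the lowest fold changes rested on transcripts nearly absent from the ampulla. CLDN5, a tight-junction gene of endothelium, had 0 counts in the ampulla and 72.6 ± 18.6 CPM in the endometrium, at least 4254-fold. The potassium channel gene KCNJ8 was at least 2634-fold higher at 45.0 ± 9.53 CPM, and DCN, the matrix proteoglycan decorin, at least 2527-fold higher at 43.1 ± 10.7 CPM. HOXA10, a homeobox gene of the uterus, had 1 count in the ampulla libraries and 123 ± 16.3 CPM in the endometrium, a ratio of 21552 with a counting interval of 3868 to 851271. The neuropeptide receptor gene QRFPR had 2 counts, a ratio of 10159 with an interval of 2812 to 83886. HOXA11 gave -13.31 ± 0.46, the water channel AQP1 gave -12.78 ± 0.44 and the nuclear receptor RORB gave -12.77 ± 0.40, with endometrial levels of 230 ± 15.8, 441 ± 218 and 518 ± 71.0 CPM. All 8 were lower in the ampulla of 5 of 5 heifers.

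Ciliated epithelium genes formed the largest epithelial group, and 33 of 38 tested members rose in the ampulla and 0 fell (34 and 0 adjusted over the list alone, counts given here only where they differ). The ciliary microtubule gene TEKT1 stood at 532 ± 52.7 CPM in the ampulla and 47.0 ± 10.6 in the endometrium, a log2 fold change of 3.57 ± 0.19. TEKT4 rose by 3.54 ± 0.21 and the cilia gene CFAP53 by 2.87 ± 0.16. The list gave a camera adjusted p of 1.70e-14, and an adjusted p = 0.11 with an estimated correlation. Among 8 oviduct secretory genes, 5 rose and 2 fell, with a median of 3.44 and an adjusted p of 0.037 (adjusted p = 0.216 with an estimated correlation). OVGP1, the oviduct-specific glycoprotein, rose by 6.15 ± 0.37, KRT23 by 6.05 ± 0.46 and mesothelin, MSLN, by 6.10 ± 0.53 from 39.7 ± 56.5 CPM, with 793 in the contralateral mid horn library of heifer 10882, to 1280 ± 770. The OVGP1 feature reached only 6.08 ± 1.95 CPM in the ampulla.

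Of 15 general epithelium genes, 12 rose and 2 fell (12 and 3 adjusted over the list alone), with a median of 1.49 and a camera adjusted p of 0.000995 (adjusted p = 0.238 with an estimated correlation). The keratins KRT18 and KRT8 rose by 2.92 ± 0.16 and 2.31 ± 0.14, the adhesion gene EPCAM by 1.68 ± 0.15 and the claudin CLDN3 by 1.95 ± 0.19. The library of heifer 10882 that carried oviduct transcripts lies on the endometrial side of this difference. Endometrial gland genes went both ways, with 6 of 13 higher and 4 lower (6 and 5 adjusted over the list alone), a median of 0.25 and an adjusted p of 0.464. Among them MSX1, a homeobox gene, fell by 5.84 ± 0.31, while FOXA1, CXCL17 and KLF5 rose by 5.86 ± 0.53, 4.74 ± 0.31 and 1.17 ± 0.16.

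All 16 stromal and all 11 endothelial genes tested fell in the ampulla. The collagen genes COL6A1 and COL1A2 gave -12.76 ± 0.37 and -8.44 ± 0.25, COL1A2 standing at 20482 ± 4841 CPM in the endometrium and 58.7 ± 15.0 in the ampulla. VIM, the intermediate filament of mesenchymal cells, gave -9.61 ± 0.30 and the matrix glycoprotein FBLN1 -5.68 ± 0.22. The stromal median was -8.62, or -8.42 with transcripts absent from the ampulla set at their bound, with a camera adjusted p of 3.21e-14, and an adjusted p = 0.000319 with an estimated correlation. Of the endothelial genes, the receptors TIE1, FLT1 and ROBO4 gave -9.00 ± 0.27, -5.82 ± 0.19 and -9.76 ± 0.32, and PLVAP, of the diaphragms of fenestrated vessels, gave -10.21 ± 0.31. Their median was -9.00, with an adjusted p of 3.78e-10 and an adjusted p = 0.00206 with an estimated correlation.

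Smooth muscle genes fell in 14 of 15 cases and 1 rose. The median was -5.12, or -4.63 with absent transcripts at their bound (camera adjusted p 1.42e-05; adjusted p = 0.11 with an estimated correlation). The contractile genes LMOD1 and CNN1 gave -8.98 ± 0.32 and -8.16 ± 0.37. Of 16 leukocyte genes 12 fell and 2 rose. Their median was -1.96, with an adjusted p of 0.0027, and an adjusted p = 0.125 with an estimated correlation. ITGAM and CSF1R, of myeloid cells, gave -4.59 ± 0.33 and -2.47 ± 0.20, the T cell gene CD5 -2.43 and the granzyme GZMB -4.82 ± 0.43.

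Among the other cell types that a sample could hold, mesothelial genes rose in 3 of 5 cases and fell in 1, with a median of 2.71 and an adjusted p of 0.052. Of these ALDH1A2, which makes retinoic acid, rose by 2.91 ± 0.34 to 746 ± 110 CPM, the transcription factor WT1 rose by 2.71 ± 0.41, and UPK3B fell by 0.73 ± 0.30 (adjusted p 0.0356, and 0.058 without the heifer block). Ovarian follicle and luteal genes gave 2 of 6 higher and 3 lower (median -0.64, adjusted p 0.667). The steroidogenic genes HSD17B1 and STAR fell by 2.92 ± 0.29 and 1.18 ± 0.26 and CYP11A1 rose by 1.17 ± 0.19. Of 3 erythroid genes, too few for a set test, HBQ1 rose by 1.01 ± 0.12, while the haemoglobin gene HBB fell by 4.64 ± 0.68.

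HOX genes, which pattern the tract from front to back, were mostly higher in the endometrium: 19 of 29 tested fell and 5 rose in the ampulla (20 and 5 adjusted over the list alone). HOXD10 and HOXD11 had ratios of 4045, with an interval of 1120 to 33405, and of 3208, with an interval of 888 to 26492, in favour of the endometrium, and HOXD9 fell by 7.67 ± 0.27. The list's median was -2.64, with a camera adjusted p of 0.00014 and an adjusted p = 0.00177 with an estimated correlation. Müllerian duct regulators fell in 12 of 16 cases and rose in 4, with a median of -2.07 and an adjusted p of 0.00602 (adjusted p = 0.0216 with an estimated correlation). LEF1, which mediates WNT signals, fell by 6.73 ± 0.40, the forkhead gene FOXC1 by 3.65 ± 0.22 and WNT5A by 3.99 ± 0.24.

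Of 16 hormone receptors 7 fell and 1 rose, with a median of -0.11, a mean of -1.51 and an adjusted p of 0.112. The growth hormone receptor GHR fell by 5.65 ± 0.31, the oxytocin receptor OXTR by 9.34 ± 0.54, the prostaglandin receptor PTGDR by 4.26 ± 0.31 and the progesterone receptor PGR by 2.31 ± 0.22. In prostaglandin synthesis and transport 4 of 9 genes fell and 0 rose (median -0.37, adjusted p 0.0718). These were the transporter SLCO2A1 at -5.75 ± 0.34, the synthases PTGES at -5.60 ± 0.39 and PTGS2 at -5.07 ± 0.44, and the degrading enzyme HPGD at -1.90 ± 0.29. Immediate early genes fell in 11 of 18 cases and 0 rose, with a median of -1.32 and an adjusted p of 0.037 (adjusted p = 0.537 with an estimated correlation, 0.0567 without the heifer block and 0.052 without the 3 doubted libraries). SOCS3, KLF2 and DUSP1 gave -1.91 ± 0.28, -1.42 ± 0.21 and -1.23 ± 0.19, and FOSL1, with 3 counts in the ampulla, gave a ratio of 22.2 with an interval of 7.59 to 108. Proliferation genes gave 3 of 16 higher and 8 lower (3 and 9 adjusted over the list alone), a median of -0.69 and an adjusted p of 0.219. The cyclins CCNB1 and CCNA2 fell by 3.72 ± 0.24 and 1.60.

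Transport genes went both ways. Of 23 nutrient transporters 8 rose and 10 fell, with a median of -0.08 and an adjusted p of 0.995. The amino acid carrier SLC1A4 rose by 2.29 ± 0.13, while SLC7A5, SLC1A1 and the glucose carrier SLC2A3 fell by 1.84 ± 0.15, 3.76 ± 0.31 and 4.98 ± 0.33. Of 16 ion and bicarbonate transport genes 6 rose and 5 fell (6 and 6 adjusted over the list alone). Their median was -0.53 and their mean -0.08, camera pointed up, and the adjusted p was 0.807. The sodium-proton exchanger SLC9A3 rose by 3.90 ± 0.27, and the chloride channel CFTR and the anion exchanger SLC26A6 fell by 5.53 ± 0.42 and 2.69 ± 0.22. Sperm-oviduct interaction genes rose in 9 of 14 cases and fell in 3 (median 0.73, adjusted p 0.0546). ANXA4, an annexin that binds sperm, rose by 1.80 ± 0.17 to 1214 ± 486 CPM and the integrin ITGA5 fell by 5.36 ± 0.38.

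Complement and antimicrobial genes gave 6 of 17 higher and 9 lower (7 and 9 adjusted over the list alone), with a median of -0.74 and an adjusted p of 0.692. Complement C3 rose by 3.41 ± 0.30 to 2246 ± 807 CPM and CFD by 1.99 ± 0.19, whereas C1S and C1QB fell by 6.69 ± 0.25 and 2.45 ± 0.24. Interferon-stimulated genes gave 6 of 21 higher and 4 lower (5 and 3 adjusted over the list alone). Their median of 0.02 turned to -0.06 with DESeq2 size factors, their mean was -0.01, camera pointed up, and the adjusted p was 0.63. IFI44L and IFIT2 rose by 1.11 ± 0.13 and 1.49 ± 0.18, and the chemokine CXCL10 fell by 2.01 ± 0.27. Matrix remodelling genes fell in 21 of 28 cases and rose in 6 (median -2.90, adjusted p 0.000275; adjusted p = 0.125 with an estimated correlation). The metalloproteinases MMP2, MMP14 and MMP11 gave -9.32 ± 0.40, -5.46 ± 0.25 and -5.67 ± 0.27, and the collagen crosslinking enzyme LOXL2 gave -7.81 ± 0.33. Antioxidant enzymes rose in 12 of 21 cases and fell in 6, with a median of 0.34 and an adjusted p of 0.219. The glutathione peroxidase GPX2 rose by 5.93 ± 0.44 to 331 ± 105 CPM and PRDX6 by 1.70 ± 0.12, while GPX7 and the haem oxygenase HMOX1 fell by 2.52 ± 0.15 and 2.76 ± 0.22.

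**Figure D2:**
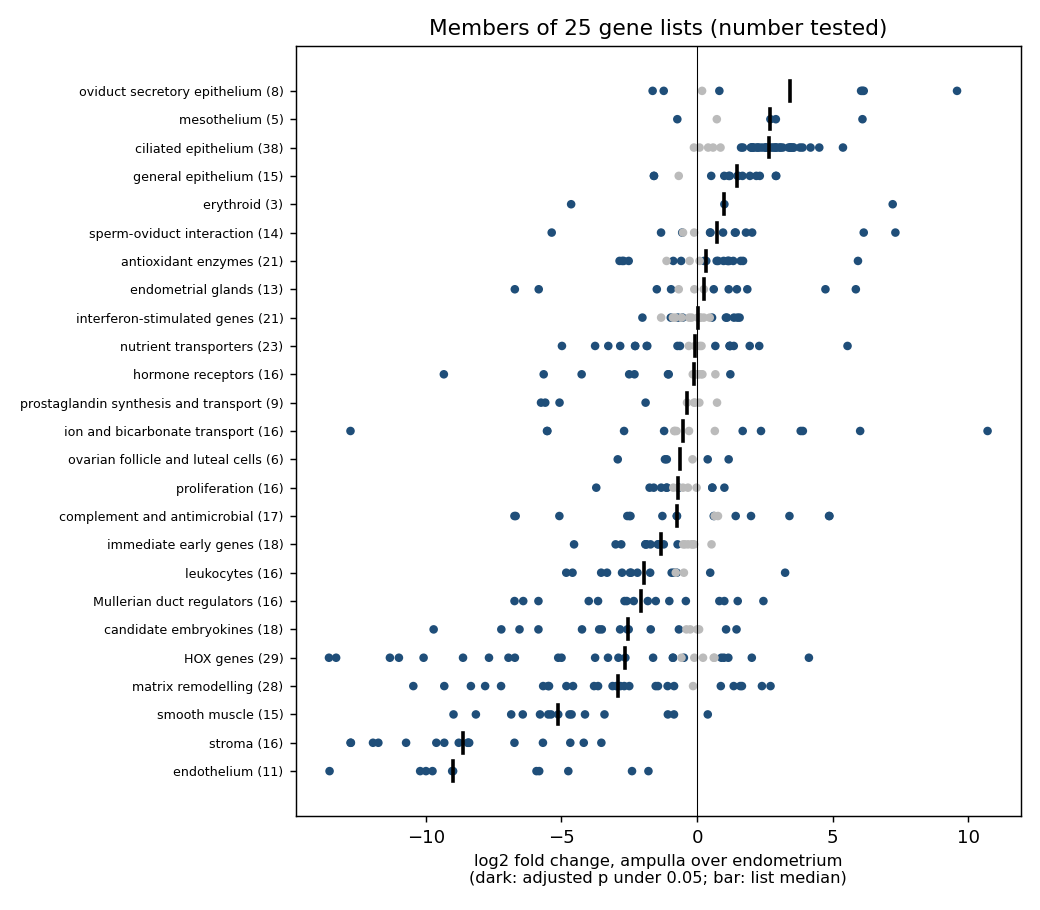
Log2 fold change of the ampulla over the endometrium for each tested member of the 25 gene lists; a point is a gene, dark points have an edgeR adjusted p under 0.05 and bars mark list medians. The ciliated epithelium has a median of 2.65 and the stroma a median of -8.62.

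Tested candidate embryokines were mostly higher in the endometrium: 12 of 18 fell and 2 rose in the ampulla, with a median of -2.55 and a camera adjusted p of 0.00209 (adjusted p = 0.122 with an estimated correlation). Members that were not tested are not covered. Genes of stroma and endothelium fell with them, by medians of -8.62 and -9.00. The chemokine CXCL12, with 3 counts in the ampulla, had a ratio of 1139 (interval 390 to 5524) toward the endometrium. The activin subunit INHBB fell by 3.61 ± 0.22, BMP2 by 2.57 ± 0.19, FGF10 by 3.51 ± 0.27, WNT7A by 5.85 ± 0.54, CCN2 by 6.55 ± 0.51, NPPC by 4.24 ± 0.56 and IL1B by 2.52 ± 0.44. FST, HBEGF and CSF2 fell by 1.71 ± 0.46, 0.67 ± 0.21 and 2.84 ± 0.96, and DKK1 by a ratio of 284 (interval 50.9 to 11210). The growth factors PDGFA and AREG rose by 1.07 ± 0.26 and 1.46 ± 0.46, at no more than 3.53 and 3.13 CPM in the ampulla. HDGF, VEGFA, FGF2 and IL6 were not called.

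Of 345 catalogued ligands 284 had a feature and 199 were tested. Of these 165 were called, 35 higher and 130 lower in the ampulla, and 166 were called adjusted over the list alone. The share called was 82.9% against 64.7% of other transcripts (Fisher's exact test, odds ratio 2.64, adjusted p 1.94e-07 over 9 comparisons), and 78.8% of the called ligands were lower in the ampulla against 54.4% of other calls. They went with the fall of stroma (-8.62), endothelium (-9.00) and smooth muscle (-5.12). At 1 CPM or more 90 ligands were detected in the ampulla and 147 in the endometrium, of which 79 were shared, 11 were seen in the ampulla alone and 68 in the endometrium alone. Where every library had to reach 1 CPM there were 64 and 90, and at a mean of 10 CPM or more 34 and 70. The upper horn, the mid horn and the body had 147, 148 and 144 detected ligands.

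The ligand features with the highest CPM in the ampulla, an order that does not rank genes by expression, were MIF, a cytokine, at 622 ± 158 CPM, GAS6, a ligand of TAM receptors, at 534 ± 79.5, the stress-induced neurotrophic factor MANF at 411 ± 288, HDGF at 350 ± 99.4 and NENF at 304 ± 43.8. Next came SEMA3C at 96.5 ± 32.1, HDGFL3 at 80.1 ± 24.7, CCN1 at 66.6 ± 89.2, the peptide neurotensin NTS at 61.5 ± 34.7 and FGF2 at 55.4 ± 10.9. Of these 10, NTS, MIF, MANF, NENF and GAS6 rose against the endometrium by 3.79 ± 0.32, 1.86 ± 0.21, 1.69 ± 0.22, 0.54 ± 0.13 and 0.28 ± 0.12, and CCN1 and HDGFL3 fell by 2.07 ± 0.42 and 0.28 ± 0.12. Without the heifer block GAS6 and HDGFL3 missed the threshold at adjusted p of 0.0502 and 0.0952. HDGF, SEMA3C and FGF2 were not called, at -0.25, -0.11 and 0.08 with edgeR adjusted p of 0.107, 0.645 and 0.609, and the FGF2 estimate was -0.02 with DESeq2 size factors.

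In the endometrium gastrin-releasing peptide, GRP, had the highest CPM of the ligand features, at 4565 ± 3235 CPM against 9.76 ± 10.7 in the ampulla, a log2 fold change of -9.33 ± 0.64. DKK3 and SFRP1, which bind or modulate WNT signals, stood at 622 ± 228 and 557 ± 85.8 CPM, with changes of -5.29 ± 0.28 and -7.32 ± 0.32. GAS6 followed at 441 ± 38.8 CPM, CCN2 at 436 ± 185, HDGF at 411 ± 72.2, CCN4 at 338 ± 116, CCN1 at 306 ± 264, NENF at 213 ± 44.2 and PROS1 at 196 ± 82.3. CCN4 gave -10.68 ± 0.44 and PROS1 -2.33 ± 0.23. The strongest changes toward the ampulla were those of GDF3 at 5.94 ± 0.53, the chemokines CCL26 at 5.79 ± 0.47 and CXCL17 at 4.74 ± 0.31, NTS and the hedgehog ligand SHH at 3.54 ± 0.34. Toward the endometrium they were those of GDF7, with 1 count in the ampulla and a ratio of 4201 (interval 754 to 165918), CCN4, WNT2 at -10.55 ± 0.39, CCL14 at -10.44 ± 0.37, CXCL12 and GRP.

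**Figure D3:**
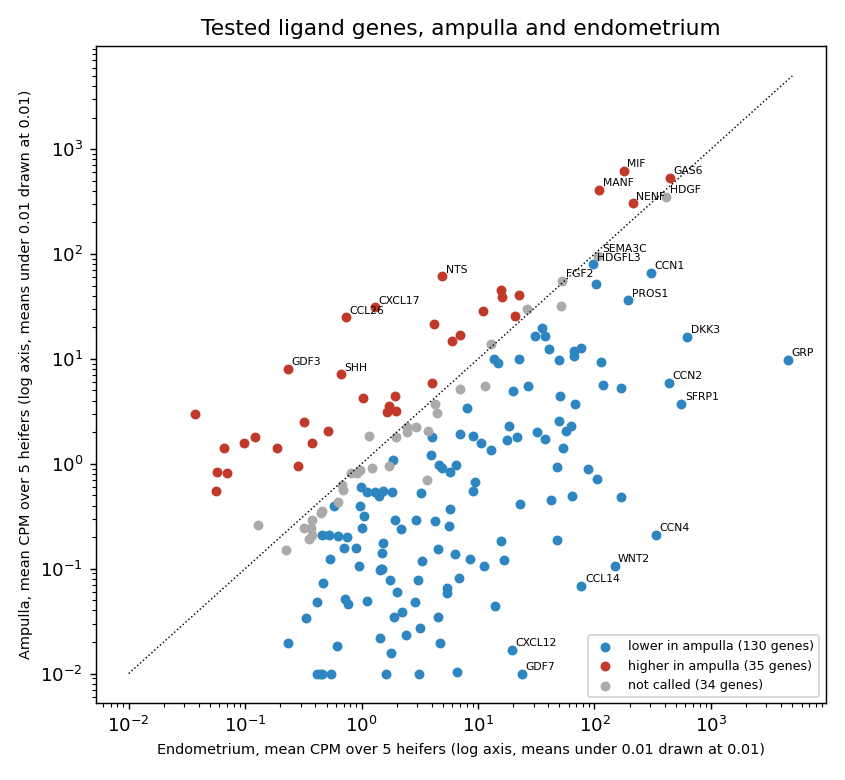
Mean CPM of each ligand gene over 5 heifers in the endometrium (x axis, log scale) and in the ampulla (y axis, log scale), with means under 0.01 CPM drawn at 0.01; each point is a tested ligand. GRP lies at 4565 CPM in the endometrium and 9.76 in the ampulla, and MIF at 178 and 622.

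By family, where the last adjusted p is that with an estimated correlation, members lower in the ampulla were most frequent among WNT inhibitors (10 of 10, median -5.77, camera adjusted p 2.97e-06, adjusted p = 0.00293) and CCN proteins (5 of 5, median -6.55, 0.000338, adjusted p = 0.0295). WNT and R-spondin ligands fell in 11 of 16 cases and rose in 3 (11 and 4 adjusted over the list alone, median -3.99, adjusted p 0.00168, adjusted p = 0.0295). BMP antagonists fell in 8 of 9 cases and rose in 1 (median -2.37, adjusted p 0.00393, adjusted p = 0.0295). Vascular ligands fell in 10 of 14 and rose in 2 (median -1.34, adjusted p 0.00543, adjusted p = 0.0296). Peptide hormones fell in 14 of 22 and rose in 4 (15 and 4 adjusted over the list alone, median -2.23, adjusted p 0.00393, adjusted p = 0.0295). The remaining calls were lost with an estimated correlation. Chemokines fell in 23 of 32 and rose in 3 (median -2.10, adjusted p 0.00238, adjusted p = 0.071), and TGF-beta ligands fell in 16 of 26 and rose in 5 (17 and 5 adjusted over the list alone, median -1.75, adjusted p 0.00623, adjusted p = 0.0532). FGF ligands fell in 5 of 9 and rose in 0 (median -0.70, adjusted p 0.0406, adjusted p = 0.0606), and TNF ligands fell in 8 of 10 and rose in 1 (median -1.86, adjusted p 0.0303, adjusted p = 0.0504).

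No call was made for EGF ligands (3 of 5 higher and 2 lower, median 1.46, adjusted p 0.439), interleukins (7 of 19 higher and 8 lower, adjusted p 0.833), neurotrophic factors (3 of 8 higher and 3 lower, median -0.21, adjusted p 0.967) and guidance ligands (1 of 9 higher and 5 lower, median -1.14, adjusted p 0.0831). For interleukins the median was -0.23 while camera pointed up. Insulin and hedgehog ligands, with 3 and 2 tested members, gave 1 higher and 1 lower each and had no set test. Counts adjusted over the list alone were the same where none is given.

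In the other comparisons all family calls were lost with an estimated correlation. Chemokines were lower in the ipsilateral ampulla by a median of -0.78 (camera adjusted p 8.35e-05; adjusted p = 0.161 with an estimated correlation), over all regions by -0.50 (0.0344; adjusted p = 0.306) and in the upper against the mid horn by -0.39 (0.0208; adjusted p = 0.464). Neurotrophic factors were lower in the body than in the upper (0.35, 0.0195; adjusted p = 0.117) and the mid horn (0.46, 0.0247; adjusted p = 0.145). On the ovulatory side WNT inhibitors were higher in the upper horn (0.65, 0.0264; adjusted p = 0.146), the mid horn (0.39, 0.0104; adjusted p = 0.135) and over all regions (0.28, 0.0443; adjusted p = 0.306). So were CCN proteins in the upper horn (1.08, 0.0125; adjusted p = 0.146) and over all regions (0.70, 0.0443; adjusted p = 0.306) and TGF-beta ligands in the mid horn (0.16, 0.0104; adjusted p = 0.135). In the interaction FGF (-0.46), WNT inhibitor (-0.52), chemokine (-0.51) and guidance ligands (-0.53) were called, with adjusted p from 0.00866 to 0.0406 and adjusted p = 0.106 to adjusted p = 0.15 with an estimated correlation. Doubted libraries lie in each of these comparisons.

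The upper against the mid uterine horn asked whether expression changes along the horn. GPC3, a glypican that modulates growth factor signals, was higher in the upper horn by 1.87 ± 0.34 (21.3 ± 10.4 against 6.27 ± 4.63 CPM, 5 of 5 heifers, edgeR adjusted p 0.0348). HOXD13, the last gene of its HOX cluster, was lower by -3.89 ± 0.61 (5 of 5 heifers, adjusted p 0.00643), with 5 counts in the 9 upper horn libraries and a ratio of 13.9 (interval 5.97 to 42.9). HOXA13 stood at 1.24 ± 1.09 against 4.44 ± 2.22 CPM without a call (log2 fold change -2.07 ± 0.43, adjusted p 0.159). The uncharacterised locus LOC112444517, named after its value was seen, was higher by 4.53 ± 0.69, which makes 3 calls, with 1049 transcripts at an unadjusted p under 0.05 and a median of 0.05. DESeq2 called 23, limma 0, edgeR without the filter 207 and a fit of the compared groups alone 1. Without the heifer block 1 was called, with GPC3 at an adjusted p of 0.363 and HOXD13 at 0.0681. The GPC3 call held only without heifer 10872 (adjusted p 0.0417) and was lost without 10882 (0.376), 11033 (0.61), 11070 (0.0898) or 11110 (0.329), within a range of 9.54e-09 to 0.816 over all alternatives. The HOXD13 call held only without 11110 (0.0487) and was lost without 10872 (0.245), 10882 (0.114), 11033 (0.111) or 11070 (0.0898), within 4.03e-06 to 0.245.

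Smooth muscle genes were the group with the highest median toward the upper horn, 1.16, with 0 of 15 called over all genes and 8 adjusted over the list alone (camera adjusted p 3.68e-09; adjusted p = 0.0799 with an estimated correlation). MYLK, CASQ2 and DES, genes of the contractile apparatus, stood at 1.54 ± 0.35, 1.79 ± 0.42 and 2.03 ± 0.47, DES with 574 ± 517 against 113 ± 30.5 CPM and higher in only 3 of 5 heifers. The upper horn libraries include the smallest one and that of heifer 10882 with 19.6% 18S. Ovarian follicle and luteal genes had a median of 0.39 (adjusted p 0.049; adjusted p = 0.173), with AMH at 0.70.

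Epithelial and secretory groups lay toward the mid horn, in which the contralateral library of heifer 10882 carried oviduct transcripts such as KRT5 at 454 CPM. General epithelium had a median of -0.47 (camera adjusted p 1.74e-08; adjusted p = 0.0809 with an estimated correlation), with 0 called and 1 lower adjusted over the list alone. KRT8, CLDN4 and KRT7 stood at -0.67 ± 0.18, -0.67 ± 0.25 and -0.74 ± 0.27. Oviduct secretory genes had a median of -0.50 (0.049; adjusted p = 0.239 with an estimated correlation and 0.0795 without the heifer block), with OVGP1 at -1.81, MSLN at -1.69 and KRT23 at -0.78, and without that library KRT23 stood at 0.15. Without the 3 doubted libraries, the secretory call was lost (0.164), as were those of the ovarian genes (0.355) and the nutrient transporters (0.105). Endometrial gland genes had a median of -0.18 (0.032; adjusted p = 0.173, and 0.255 without heifer 11110, which stood apart) with the protease PRSS22 at -0.71, and sperm-oviduct genes one of -0.39 (0.00103; adjusted p = 0.0799) with ANXA1 at -0.52. Antioxidant enzymes had a median of -0.17 (0.00053; adjusted p = 0.173), with GPX2 at -1.89 ± 0.54 and 1 lower adjusted over the list alone.

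Matrix remodelling genes had a median of -0.25 (camera adjusted p 1.55e-06; adjusted p = 0.0799 with an estimated correlation), with 3 lower adjusted over the list alone, among MMP9 at -2.70 ± 0.66, the plasminogen activator PLAT at -0.68 ± 0.19 and MMP1 at -2.92 ± 0.95. Complement genes had a median of -0.46 (0.0131; adjusted p = 0.0799), with 1 higher and 2 lower adjusted over the list alone and C7 at 0.86 ± 0.21, CFB at -1.22 and LYZ at -0.65. HOX genes had a median of -0.02, or 0.01 with DESeq2 size factors, and a mean of -0.23 (0.0346; adjusted p = 0.0799). Of these 1 was called lower and 3 adjusted over the list alone. Smaller shifts toward the mid horn were seen for embryokines (median -0.29, 0.0145; adjusted p = 0.173), leukocytes (-0.23, 0.0148; adjusted p = 0.173, and 0.50 without heifer 11070, which stood apart), interferon-stimulated genes (-0.21, 0.0249; adjusted p = 0.398), ion transport (-0.27, 0.0266; adjusted p = 0.139) and nutrient transporters (-0.07, 0.049; adjusted p = 0.173). In these CSF2 stood at -2.31 ± 0.81, GZMB at -0.74, IFIH1 at -0.38, CA2 at -1.48 and SLC1A5 at -0.43. No ligand was called with edgeR, and 6 were adjusted over the list alone.

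The upper horn against the uterine body compared both ends of the uterus. HOXD13 was lower in the upper horn by -7.10 ± 0.62 (0.0229 against 3.67 ± 2.52 CPM, ratio 137, interval 58.6 to 421) and HOXA13 by -3.59 ± 0.49 (1.24 ± 1.09 against 11.9 ± 5.44 CPM). Both held in 5 of 5 heifers and under each of the 16 alternatives, with edgeR adjusted p of 9.13e-08 and 0.000293. PENK, the precursor of enkephalin peptides, was higher in the upper horn by 1.86 ± 0.36 (81.6 ± 101 against 15.5 ± 8.68 CPM, adjusted p 0.0489). The uncharacterised locus LOC101907241, named after its value was seen, was lower by -2.56 ± 0.39. There were 4 calls in all, 1 higher and 3 lower, with 1927 transcripts at an unadjusted p under 0.05, and DESeq2 called 12, limma 5 and edgeR without the filter 150. The PENK call was lost without any 1 heifer, at an adjusted p of 0.138 without 10872, 0.226 without 10882, 0.492 without 11033, 0.201 without 11070, 0.157 without 11110 and 0.619 without the heifer block, within a range of 9.16e-08 to 0.619 over all alternatives. The count fell to 2 without heifer 10882 or 11070.

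Smooth muscle genes had a median of 0.71 toward the upper horn, with 0 called and 4 adjusted over the list alone (camera adjusted p 0.0167; adjusted p = 0.549 with an estimated correlation). CASQ2, DES and the calponin CNN1 stood at 1.89 ± 0.55, 1.86 ± 0.60 and 1.07 ± 0.35. HOX genes had a median of -0.15 and a mean of -0.57, 2 called lower and 3 adjusted over the list alone (0.0202; adjusted p = 0.0998), with HOXC11 at -1.19 ± 0.38. Epithelial groups lay slightly toward the upper horn: general epithelium had a median of 0.32 (0.0202; adjusted p = 0.549) with PERP at 0.49, and endometrial glands one of 0.34 (0.0355; adjusted p = 0.549) with the trefoil factor TFF3 at 0.89 ± 0.32. Antioxidant enzymes had a median of 0.25 (0.0167; adjusted p = 0.549) with PRDX5 at 0.54 and SOD1 at 0.46. Proliferation genes had one of 0.34 (0.0467; adjusted p = 0.549 with an estimated correlation, 0.0627 without the heifer block and 0.282 without heifer 11070, which stood apart), with TOP2A at 1.40, MCM3 at 0.45 and TYMS at -1.21. The body library of heifer 11033, with 23.5% of counts on 18S, lies on the other side of each of these groups, and without it the calls of general epithelium (0.262), glands (0.0737), antioxidant (0.279) and proliferation genes (0.0525) were lost.

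The mid horn against the uterine body gave more calls than the other comparisons within the uterus. Epithelial genes were higher in the mid horn (adjusted p = 0.208 with an estimated correlation), and HOXD13 and HOXA13 were higher in the body. The mid horn holds the contralateral library of heifer 10882, in which general epithelium genes lay higher by a median of 1.04, and the body that of heifer 11033 with 23.5% 18S. HOXD13 stood at 0.373 ± 0.25 against 3.67 ± 2.52 CPM (log2 fold change -3.21 ± 0.44, edgeR adjusted p 0.00146) and HOXA13 at 4.44 ± 2.22 against 11.9 ± 5.44 CPM (-1.52 ± 0.45, adjusted p 0.0483), each in 5 of 5 heifers. Without the heifer block the adjusted p was 0.0178 and 0.169. Both were the called members of the HOX list, with 6 lower adjusted over the list alone, a median of -0.19 and a camera adjusted p of 0.305. The keratins KRT8, KRT7 and KRT18, the claudin CLDN4 and the desmosome gene PERP rose in the mid horn by 0.93 ± 0.22, 1.31 ± 0.34, 0.88 ± 0.24, 1.09 ± 0.30 and 0.89 ± 0.25. These were the 5 called of 15 general epithelium genes, with 11 adjusted over the list alone, a median of 0.82 and a camera adjusted p of 7.86e-07, and 8.32e-07 without that body library.

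In all 767 transcripts were called, 91 higher and 676 lower in the mid horn, of which 82 and 261 carried a symbol. At least 2-fold changes were seen for 20 higher and 651 lower ones, 4833 had an unadjusted p under 0.05, and the median over all was -0.06, which DESeq2 size factors moved by -0.10. Besides the genes above, the highest were KRT5 at 4.12 ± 1.15 (51.9 ± 98.2 against 0.702 ± 0.532 CPM), the galectin LGALS7B at 1.54 ± 0.44, CLDN6 at 1.52 ± 0.46, MGST1 at 0.97 ± 0.29 and the tubulin TUBA4A at 0.88 ± 0.21. The mean of KRT5 in the mid horn comes from the contralateral library of heifer 10882. The lowest were RHBDF1 at -2.31 ± 0.59, the dynactin subunit DCTN1 at -2.26 ± 0.65, TNKS1BP1 at -2.16 ± 0.46, the forkhead gene FOXP1 at -2.11 ± 0.48, CUL9 at -1.98 ± 0.51, ZC3H14 at -1.97 ± 0.49, PRDM1, a regulator of plasma cells, at -1.97 ± 0.49 and the RNA-binding HNRNPH3 at -1.93 ± 0.52. All 16 had the same sign in 5 of 5 heifers, with adjusted p between 0.0408 and 0.0497. Most calls lay close to the threshold: the count was 1835 without heifer 10872, 1045 without 11110, 2 without 11033, 0 without 10882 or 11070, and 1 without the contralateral mid horn library of 10882 alone. Without the heifer block HOXD13 alone was called, and the other genes named by fold change and the 17 called list members and ligands outside the HOX list had adjusted p from 0.155 to 0.313. The count was 99 with limma, 2714 with DESeq2, 2057 without the filter, 3028 with the compared groups alone, 1 with both sides summed per heifer and 1 without the body library of heifer 11033.

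Among other groups, antioxidant enzymes had a median of 0.46 with 1 called, PRDX6 at 0.60 ± 0.18 (adjusted p 0.0497), and 8 adjusted over the list alone (camera adjusted p 2.32e-05; adjusted p = 0.208 with an estimated correlation). TXN2 stood at 0.58. Endometrial glands had a median of 0.46 with 1 called, TFF3 at 1.10 ± 0.32, and 2 adjusted over the list alone (0.00445; adjusted p = 0.208). Leukocytes had a median of 0.48 (0.00936; adjusted p = 0.272) with LYZ at 0.74, complement 0.54 (0.0328; adjusted p = 0.208) with CFD at 0.73, and sperm-oviduct genes 0.46 (0.0374; adjusted p = 0.272) with CALR at 0.62. Embryokines had a median of 0.44 (0.0277; adjusted p = 0.272), with WNT7A at 1.37 and none called. Proliferation genes had a median of 0.41 (0.0432; adjusted p = 0.297), while the thymidylate synthase TYMS fell by 2.09 ± 0.56, with 3 higher and 2 lower adjusted over the list alone. Without the body library of heifer 11033 the calls of complement (0.0652), embryokine (0.0652) and sperm-oviduct genes (0.0899) were lost, the latter also without the mid horn library of 10882 (0.0633).

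Single called members of other lists were chosen for mention after their values were seen: MMP9 at 3.31 ± 0.80 (7.68 ± 12.2 against 0.458 CPM), SLC26A6 at -0.92 ± 0.26, UPK3B at -1.39 ± 0.40, PAX2 at -1.93 ± 0.52, TAGLN at -1.99 ± 0.55 and COL5A1 at -2.82 ± 0.66. Of the ligands 3 were called and all were lower in the mid horn, while 0 were called adjusted over the list alone. They were TNFSF10, a death receptor ligand, at -1.78 ± 0.46, the WNT inhibitor DKK2 at -1.58 ± 0.46 and ANGPTL8 at -1.82 ± 0.54, in 5, 4 and 4 of 5 heifers and, for the latter pair, named after their values were seen. For all genes named here the call was lost in at least 1 alternative, with adjusted p up to 0.367 for the keratins, PRDX6 and TFF3.

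Ipsilateral against contralateral ampulla asked whether the side of ovulation marks the oviduct. On the ovulatory side SPON2, a secreted matrix protein, rose by 2.43 ± 0.39 (206 ± 146 against 36.1 ± 21.0 CPM), the metalloproteinase inhibitor TIMP2 by 1.88 ± 0.30 (3779 ± 1781 against 1075 ± 672 CPM) and IGFBP3, a carrier of insulin-like growth factors, by 1.79 ± 0.32 (185 ± 147 against 54.4 ± 26.1 CPM). The edgeR adjusted p was 0.0046, 0.0046 and 0.027, and all 3 were higher in 5 of 5 heifers. There were 3 edgeR calls in all, 150 without the filter and 0 with the compared groups alone, with 1250 transcripts at an unadjusted p under 0.05, while limma called 5 and DESeq2 17. SPON2 was lost without heifer 10872 (adjusted p 0.165) or 11033 (0.144), within a range of 1.40e-20 to 0.738 over all alternatives, and TIMP2 without 10872 (0.165) or 11070 (0.0539), within 1.03e-14 to 0.36. IGFBP3 held only without 11110 (0.0472) and was lost without 10872 (0.0726), 10882 (0.327), 11033 (0.283) or 11070 (0.203), within 1.88e-10 to 0.633. Without the heifer block 1 transcript was called, with TIMP2 at 0.166 and IGFBP3 at 0.157, and without heifer 10872 or 11070 the count was 0 and 1.

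**Figure D4:**
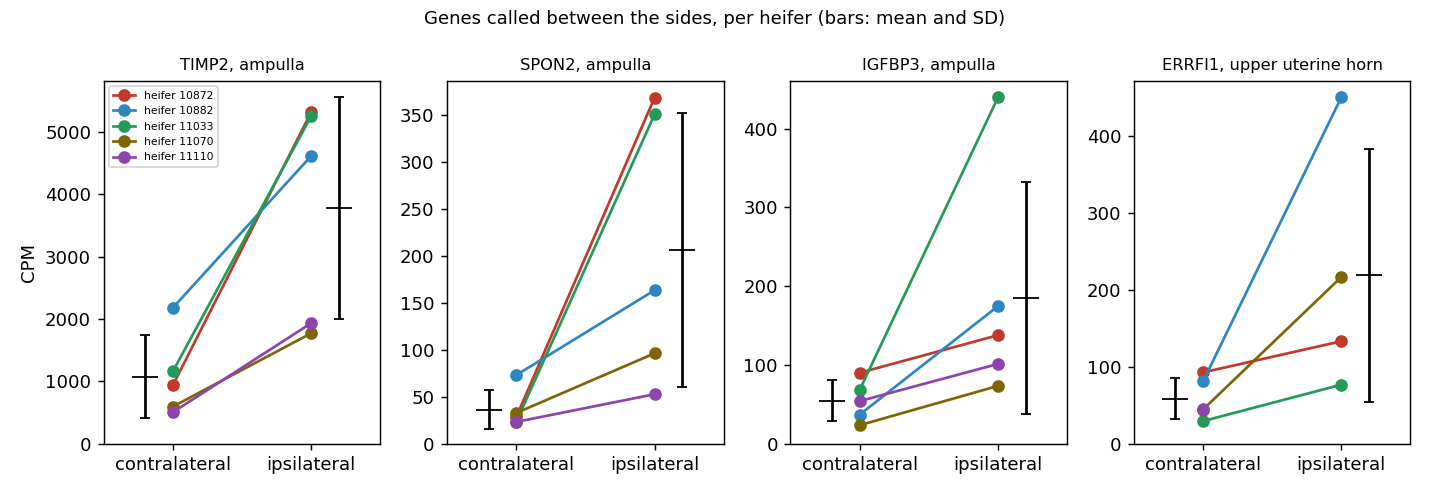
CPM of SPON2, TIMP2 and IGFBP3 in the ampulla and of ERRFI1 in the upper uterine horn by side; points joined by a line are libraries of 1 heifer, and bars show mean and SD. SPON2 averages 206 CPM on the ipsilateral and 36.1 CPM on the contralateral side.

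Oviduct secretory genes had a median of 0.68 toward the ovulatory ampulla, with 0 called and 1 adjusted over the list alone (camera adjusted p 0.0234; adjusted p = 0.377 with an estimated correlation). The phosphate carrier SLC34A2, the folate receptor FOLR1 and PAX2 stood at 1.18 ± 0.35, 0.70 and 0.83. Nutrient transporters had a median of 0.32 (0.0234; adjusted p = 0.377), with 2 adjusted over the list alone and the glucose carriers SLC2A4 and SLC2A10 at 1.89 ± 0.39 and 1.45. SLC38A1, with 3 counts on the contralateral side, gave a ratio of 9.14 (interval 3.13 to 44.3). Leukocyte genes lay toward the contralateral side with a median of -0.29 (0.0184; adjusted p = 0.377) and 1 lower adjusted over the list alone. CD3D and LYZ both stood at -0.67, and GZMB, with 4 counts on the ipsilateral side, was 8.41 times higher contralaterally (interval 3.29 to 30.9). The contralateral libraries include that of heifer 11070 with the fewest features and that of heifer 11110 with 11.1% 18S. Without heifer 11110, 0 of the gene lists were called. No ligand was called with edgeR, and 1 was adjusted over the list alone.

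Ipsilateral against contralateral upper horn asked the same of the tip of the uterus, with 4 heifers sampled on both sides. ERRFI1, an inhibitor of EGF receptor signalling, rose on the ovulatory side by 1.81 ± 0.30 (219 ± 164, n = 4, against 58.4 ± 26.9 CPM, n = 5; 4 of 4 heifers, edgeR adjusted p 0.016). There was 1 edgeR call (173 without the filter, 0 with the compared groups alone, 22 by DESeq2, 0 by limma) and 1188 transcripts at an unadjusted p under 0.05. Immediate early genes lay toward the ovulatory side with a median of 1.59, 0 of 18 called and 11 adjusted over the list alone (camera adjusted p 8.31e-13; adjusted p = 0.115 with an estimated correlation). Means by heifer ran from 0.137 to 3.16, and handling at collection was not tested. The contralateral side holds the smallest library and that of heifer 10882 with 19.6% 18S. FOSB stood at 4.54 ± 0.99 (66.2 ± 77.0 against 1.01 ± 0.845 CPM), SOCS3 at 2.01 ± 0.47 and BTG2 at 2.11 ± 0.50. The ERRFI1 call was lost without heifer 10882 (adjusted p 1), 11070 (0.854) or 11110 (0.146) and without the heifer block (0.115), within a range of 1.28e-07 to 1 over all alternatives. The count was 8 without heifer 10872 and 0 without the 3 doubted libraries.

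Smooth muscle genes had a median of 0.48 and a mean of 1.05 toward the ovulatory side, with 5 adjusted over the list alone (camera adjusted p 8.99e-06; adjusted p = 0.115 with an estimated correlation) and LMOD1 at 1.60 ± 0.33, TAGLN at 3.16 ± 0.76 and DES at 2.56 ± 0.72. Matrix remodelling genes had a median of 0.49 (9.17e-06; adjusted p = 0.115), with 4 adjusted over the list alone and the proteases ADAMTS4 and ADAMTS5 at 2.47 ± 0.55 and 1.02 ± 0.28 and TIMP3 at 0.93 ± 0.25. Embryokines had a median of 0.50 (0.000456; adjusted p = 0.115, and 0.185 without heifer 11070), 4 adjusted over the list alone. The EGF receptor ligands HBEGF and AREG stood at 1.30 ± 0.35 and 2.66 ± 0.85 and IL6 at 2.37 ± 0.77. Ciliated epithelium genes lay toward the contralateral side with a median of -0.44 (0.000916; adjusted p = 0.676) and DNAI3 at -1.50 and CDHR3 at -0.64. The contralateral libraries of heifers 11033 and 10882 bear on these groups too.

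Ipsilateral against contralateral mid horn gave no edgeR call. At an unadjusted p under 0.05 there were 513 transcripts, the smallest adjusted p was 0.928, DESeq2 called 21, limma 0 and edgeR without the filter 140. Ciliated epithelium genes had a median of -0.61 toward the contralateral side (camera adjusted p 1.08e-11; adjusted p = 0.22 with an estimated correlation), with RSPH4A at -1.39 ± 0.44, STOML3 at -1.92 and SNTN at -0.98. Oviduct secretory genes had a median of -1.18 and a mean of -1.89 (0.00019; adjusted p = 0.0615), with 4 lower adjusted over the list alone. CRISP3 had 0 counts on the ipsilateral side, at least 118-fold less, and KRT23 and OVGP1 stood at -2.57 and -2.15. General epithelium had a median of -0.33 (0.00374; adjusted p = 0.443) with KRT18 at -0.60 and KRT8 at -0.41. In the contralateral library of heifer 10882, which bears on each of these 3 groups, CRISP3 stood at 15.8 CPM against 0 in the other uterine libraries of that heifer, and its general epithelium genes lay higher by a median of 1.04. Without that library the general epithelium call was lost (0.0554) and the other 2 held. The general epithelium call was also lost without heifer 10882 (camera adjusted p 0.328) or 11033 (0.073).

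Toward the ovulatory mid horn, stromal genes had a median of 0.39 (camera adjusted p 1.70e-05; adjusted p = 0.0615 with an estimated correlation) with COL1A2 at 0.63 ± 0.26 and DCN and COL6A1 both at 0.49. Endothelial genes had one of 0.33 (0.000158; adjusted p = 0.0615) with VWF at 1.32 and FLT1 at 0.33. Matrix remodelling genes had one of 0.30 (0.00285; adjusted p = 0.325) with ADAMTS5 and MMP14 both at 0.60 and TIMP3 at 0.40. Smooth muscle had one of 0.35 (0.0168; adjusted p = 0.443) with MYLK at 0.93 and PGM5 at 0.46, and hormone receptors one of 0.14 (0.0251; adjusted p = 0.0615) with GHR at 0.71 and IGF2R at 0.38. The contralateral library of heifer 10882, whose endometrium transcripts stood at a median ratio of 0.688 to that heifer's other uterine libraries, bears on these 5 groups too. Without it all 5 calls held, and without the 3 doubted libraries those of smooth muscle (0.0573) and hormone receptors (0.0545) were lost. The transcripts with the lowest p were SEMA5A at 1.35 ± 0.45, SINHCAF at 1.85 ± 0.67 and PLEKHG1 at 1.93 ± 0.70 on the ipsilateral side, and C4H7orf78 at -2.85 ± 0.63, ICAM5 at -2.37 ± 0.56 and P2RX2, with 0 counts ipsilaterally and at least 46.6-fold less, on the other. Their adjusted p was 0.928 for C4H7orf78 and P2RX2 and 1 for the others. ICAM5 and P2RX2 rest mostly on that library: heifer 10882 differed by -4.40 and -6.02, the nearest other heifer by -1.53 and -0.952.

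Over all regions the side of ovulation gave no edgeR call, with 2299 transcripts at an unadjusted p under 0.05, a smallest adjusted p of 0.13, 100 DESeq2 calls, 507 without the filter and 0 by limma. Immediate early genes lay toward the ovulatory side with a median of 0.69, with 0 called and 11 adjusted over the list alone (camera adjusted p 9.36e-07; adjusted p = 0.292 with an estimated correlation). FOSB, EGR1 and BTG2 stood at 2.38 ± 0.56, 1.69 ± 0.40 and 1.01. Matrix remodelling had a median of 0.42 with 7 adjusted over the list alone (4.23e-05; adjusted p = 0.292), with ADAMTS5 at 0.57 and ADAMTS1 at 0.69. Stroma had a median of 0.26 with 2 adjusted over the list alone (0.0134; adjusted p = 0.292), with SPARC at 0.52 ± 0.14 and COL1A2 and MMP2 both at 0.48. Hormone receptors had a median of 0.14 with 2 adjusted over the list alone (0.0438; adjusted p = 0.288), with PGR at 0.62 ± 0.19 and GHR at 0.72 ± 0.23. Ciliated epithelium lay toward the contralateral side with a median of -0.41 and 8 lower adjusted over the list alone (1.94e-06; adjusted p = 0.306), with RSPH4A at -0.93 and LRRC23 at -0.76.

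Smaller shifts toward the ovulatory side were those of smooth muscle (median 0.35, 0.00465; adjusted p = 0.306 with an estimated correlation) with LMOD1 at 0.65 and CNN1 at 0.63, and endothelium (0.27, 0.0453; adjusted p = 0.306, and 0.0596 without the heifer block) with TEK at 0.36 and TIE1 at 0.42. Embryokines had a median of 0.20 with 1 adjusted over the list alone (0.0453; adjusted p = 0.306 with an estimated correlation and 0.0676 without the block), with HBEGF at 0.68, INHBB at 0.41 and the natriuretic peptide NPPC at -1.26. Nutrient transporters had one of 0.05 with 4 adjusted over the list alone (0.0478; adjusted p = 0.306 with an estimated correlation and 0.0596 without the block), with SLC38A1 at 1.45 and SLC2A4 at 0.75. The transcripts with the lowest p were the adrenergic receptor ADRA2C at 1.89 ± 0.34 (adjusted p 0.13, 4 of 5 heifers), the kinase SIK1 at 0.74 ± 0.16 (0.199, 4 of 5) and IGFBP3 at 0.86 ± 0.19 (0.199, 5 of 5), with PIEZO2 at -1.29 ± 0.31 (0.238, 3 of 5), CETN4 at -0.73 ± 0.19 and SPEF2 at -0.94 ± 0.24. The contralateral libraries include the 3 doubted ones, and the endothelium call was lost without that of heifer 10882 (0.0954). No ligand was called with edgeR in this comparison or in either horn region, and 0 were adjusted over the list alone.

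The interaction asked whether the side of ovulation acts differently in the ampulla than in the horn, and gave no edgeR call. There were 918 transcripts at an unadjusted p under 0.05 7 DESeq2 calls, 116 without the filter and 0 by limma. SPON2 and TIMP2 had the lowest p, with side differences larger in the ampulla by 2.52 ± 0.46 and 1.91 ± 0.36 (adjusted p 0.076 for both, 1.16e-14 to 0.847 and 1.29e-09 to 0.841 over all alternatives). The RNA-binding YBX2, RASA4B and SEC11C followed at 1.55 ± 0.36, 1.14 ± 0.26 and 1.32 ± 0.31 (adjusted p 0.411). Ciliated and oviduct secretory genes had a higher side difference in the ampulla than in the horn, with medians of 0.48 and 0.99, and smooth muscle, leukocytes, immediate early genes and embryokines a lower one, with medians of -0.43, -0.48, -0.17 and -0.33. Their camera adjusted p ran from 0.000243 to 0.0436. With an estimated correlation each call was lost: secretory adjusted p = 0.122, leukocyte 0.25, smooth muscle 0.392, embryokine 0.487, ciliated and immediate early 0.70. Without the contralateral mid horn library of heifer 10882 the ciliated call alone was lost (0.339). Without that heifer smooth muscle (0.0795), immediate early (0.517) and embryokine calls (0.0795) were lost too, and without 11110 the latter pair.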

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

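Chosen only after the result was seen were the tests of a label exchange and of the body library of heifer 11033, and all 3 tests on immunoglobulin G. Of 137 groups of values examined for a heifer or library far from the others, 12 stood out, where chance gives about 1 in 20. The measure is the gap to the nearest value over the whole range. In heifer 10882 the difference between the ampulla and the endometrium was small for LRCOL1 (0.718, at 4.60 against 7.74 to 8.97 on the log2 scale in the others) and TMEM151A (0.838), and the side difference in the mid horn stood apart for P2RX2 (0.842) and ICAM5 (0.783). FOXP1 between the mid horn and the body stood apart in heifer 11033 (0.719). Of list means, endometrial glands in heifer 11110 (0.848) and leukocytes in heifer 11070 (0.822) stood apart between the upper and the mid horn, and proliferation genes in heifer 11070 between the upper horn and the body (0.811). The 18S share stood apart in 1 library each of the contralateral upper horn (0.961), the ipsilateral upper horn (0.891) and the body (0.847). The share of immunoglobulin G transcripts in the endometrium stood apart in heifer 10882 (0.949), at 1.33% of counts against at most 0.0724%. The interaction set the side difference of the ampulla apart from that of the horn for ciliated (camera adjusted p 0.0261), secretory (0.000243), smooth muscle (0.000539), leukocyte (0.000546), immediate early (0.0298) and embryokine genes (0.0436), each lost with an estimated correlation and the ciliated one also without the 3 doubted libraries (0.777).

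The contralateral mid horn library of heifer 10882 carried oviduct transcripts, among them MSLN at 793 CPM against 9.88 in the other uterine libraries of that heifer. A label exchanged with an ampulla library was argued against, as transcripts of the endometrium kept a median ratio of 0.688 to those other libraries over 190 transcripts. A larger share of the endometrium's own epithelium was argued against too, since general epithelium genes rose by a median of 1.04 (SD 0.511, 12 members) where the ampulla transcripts rose by 4.71. Ampulla tissue or RNA mixed into the library is a candidate explanation that stays open: 97.7% of 43 ampulla transcripts gave an ampulla share within 2-fold of their median share of 33.0%. The design gives no biological explanation for 1 library, and none was tested.

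The 676 transcripts higher in the body than in the mid horn differed by a median of 1.76. Without the body library of heifer 11033, 1 call was left. As the whole cause it was argued against: as many transcripts chosen with 1 of the other 4 heifers left out exceeded all transcripts in that heifer by a median that averaged 0.814 (SE 0.26). At an equal depth of 11251957 counts, body libraries detected 22982 ± 2009 transcripts and mid horn libraries 20412 ± 1224. The slope on that number over 19 horn libraries predicted a difference of 0.388 (jackknife SE 0.181), and with the number as a covariate the median was 0.752 and 1 call was left. The number of transcripts a library detects and the region cannot be told apart here, because the horn libraries alone predict a small part of the difference while the covariate removes most of it, and a difference of tissue stays open as untested.

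IGHG1 stood at 7218 CPM in the endometrium of heifer 10882 and at no more than 282 in the others, and at 35.5 against at most 31.2 in the ampulla. JCHAIN, MZB1, POU2AF1, PRDM1 and SDC1 had been seen before the list of 9 plasma cell genes was written. Blood left in the samples was argued against by HBB, which lay at a log2 difference of -3.24 from the highest other heifer. Plasma cells in the endometrium and an allele that fits the reference better cannot be told apart. Of the 9 genes 6 lay above every other heifer, JCHAIN at 1229 against at most 317 CPM, with a median log2 difference of 0.818 (bootstrap SE 0.735), but the genes seen before decide nothing. Of the 4 others SLAMF7 and CD79A lay above and PIM2 and FKBP11 did not, which are too few. The design names no difference between heifers, so no other biological explanation was tested.

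For each comparison 60 splits were drawn, the real one included. Chance could be excluded for the ampulla against the endometrium (1 split with 11198 calls, highest other 1098). For the mid horn against the body (767 calls, highest other 1) splits cannot decide, as 1 call was left with sides summed per heifer. For the upper against the mid horn (1 split with 3 calls, highest other 2) the margin was too small to decide. Chance could not be excluded for the upper horn against the body (6 splits with at least 4 calls, highest other 1730), where 3 of 30 within heifers reached 4 calls (highest other 11). Nor could it for the sides of the upper horn (10 splits with at least 1 call, highest other 12), where 4 of 16 splits within heifers reached it. For the sides of the ampulla 10 splits gave at least 3 calls (highest other 742), but the 9 others exchanged libraries across heifers. Of 16 splits within heifers only the real one reached 3 calls and the highest other gave 1, and 16 are too few for a share under 0.05. For the sides of the mid horn, the sides over all regions and the interaction the count was 0, which all 60 splits reach by definition, so they say nothing about chance (highest other 0, 2 and 35).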

How the results depend on the processing

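Chosen only after the data were seen were counts summed per gene and the omissions of named libraries and of transcripts. For the ampulla against the endometrium the count of calls stayed within 1.5 times of 11198 under each alternative, from 9523 against the upper horn alone to 13402 without a filter, and 2369 of 2413 values of named genes kept direction and side of the threshold. Elsewhere 655 of 698 did for the upper against the mid horn, 290 of 304 for the upper horn against the body, 423 of 622 for the mid horn against the body, 156 of 178, 212 of 238 and 432 of 439 for the sides of the ampulla, the upper and the mid horn, 460 of 494 over all regions and 68 of 75 for the interaction. Of the gene lists tested, 108 of 120, 108 of 150, 38 of 60, 59 of 80, 21 of 30, 44 of 50, 59 of 80, 59 of 90 and 43 of 60 values did, in the same order of comparisons. The cause of each change was not tested unless the alternative names it.

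Without a filter there were 207 calls for the upper against the mid horn, 150 for the upper horn against the body, 2057 for the mid horn against the body, 150, 173 and 140 for the sides of the ampulla, the upper and the mid horn, 507 over all regions and 116 for the interaction, over 38568 transcripts tested. In the same order the DESeq2 Wald test called 23, 12, 2714, 17, 22, 21, 100 and 7. Without the heifer block (no pairing) there were 1 for the upper against the mid horn, 1 for the mid horn against the body, 1 for the sides of the ampulla and 0 for those of the upper horn. For the ampulla against the endometrium 10551 of the 11198 calls were made without it too. Limma-voom with heifer as a random effect gave 0, 99, 5 and 0 for these 4, and fits of the compared groups alone 1, 3028, 0 and 0. The mid horn against the body also gave 1276 with DESeq2 size factors, 1 with both sides summed, 1228 without the 3 doubted libraries and 1 without the contralateral mid horn library of heifer 10882. Without the 3 doubted libraries the sides of the upper horn gave 0 calls and 8 lists, and without the body library of heifer 11033 the mid horn against the body gave 5 lists. In the endometrium 90 ligands were detected when every library had to reach 1 CPM, against 147.

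With an estimated correlation 4 gene lists were called for the ampulla against the endometrium, where the preset gave 12. It called 0 in the other 8 comparisons, where the preset gave 15, 6, 8, 3, 5, 8, 9 and 6. Some signs turned for genes that were not called. KRT23 between the upper and the mid horn, at -0.78, was 0.20 without heifer 10882 and -1.17 without 11033, 0.22 without the 3 doubted libraries and 0.15 without the contralateral mid horn library of 10882. FGF2 between the ampulla and the endometrium, at 0.08, was -0.0171 by the DESeq2 Wald test and -0.0171 with DESeq2 size factors, and ran from -0.0216 without heifer 11070 to 0.211 without 10882, with -0.0101 without 11033. SEMA3C, at -0.11, ran from -0.44 without heifer 11110 to 0.0556 without 10872.

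Without each heifer in turn, calls ran from 9741 to 11076 for the ampulla against the endometrium. The other region comparisons gave in order 0 to 2, 2 to 4 and 0 to 1835. The sides and the interaction gave in order 0 to 4, 0 to 8, 0 to 0, 0 to 1 and 0 to 0. Called ligands ran from 156 to 163 and detected ones from 89 to 94 in the ampulla and 144 to 151 in the endometrium. Called lists ran, in the order of comparisons, from 12 to 13, 8 to 14, 3 to 6, 6 to 9, 0 to 4, 4 to 9, 5 to 9, 5 to 10 and 2 to 6. The fewest came without heifer 11110 for the upper against the mid horn and the ampulla sides. For the upper horn against the body it was 11070, and over all regions and for the interaction 10882. Outside the ampulla against the endometrium, each embryokine call was lost without some heifer (up to 0.354).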

Other observations

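Chosen only after the result was seen was the test on the order of the HOX genes. The HOX genes of the ampulla and the endometrium parted by their place in the clusters. Of 18 tested genes of paralog groups 1 to 8, 5 were higher and 8 lower in the ampulla, with a median log2 fold change of -0.29. All 11 tested genes of groups 9 to 13 were lower, with a median of -8.63, beside falls of -8.62 for stroma and -9.00 for endothelium. As a hypothesis, the fold change may follow the order of the paralog groups: over 29 genes Spearman's rho was -0.83 and Pearson's r -0.79, with a permutation p of 1e-05, the smallest that 100000 permutations can give, and r was -0.80 without the 2 genes farthest from the median group. This relation is across genes, which are not independent.

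HOXD13 and HOXA13 also differed along the uterus. HOXD13 averaged 0.0229 CPM in the upper horn, 0.373 in the mid horn and 3.67 in the body, and HOXA13 averaged 1.24, 4.44 and 11.9 CPM, without a call between the upper and the mid horn (adjusted p 0.159). PENK averaged 81.6 ± 101, 46.9 and 15.5 CPM, and its call between the upper horn and the body was lost without any 1 heifer (adjusted p 0.138 to 0.492). The middle value of PENK was looked up after the calls were seen, and for all 3 genes each step was tested only as a pair of regions.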
